A study of Homo sapiens with 22 samples.

How the data were processed

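H3K27ac, the acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 22 samples labelled as glioblastoma tumour. Glioblastoma is the most malignant diffuse glioma of the adult brain. The labels put all 22 samples in 1 group and name no control tissue, treatment or outcome, so no comparison between groups was made. Per the labels' protocols, chromatin of crosslinked samples was sheared by sonication and precipitated with an antibody against H3K27ac on magnetic beads, and size-selected libraries were made for Illumina sequencing. Tumours are named here by numbers given in accession order, which carry no other information.

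The authors deposited 1 list of peaks per tumour, so replicates were not pooled. Each list has 5 columns without a header, namely chromosome, start, end, peak name and a peak score. The submitters' processing notes name Bowtie, MACS and deepTools and the hg19 genome build. Versions, the peak cutoff, the control library and the read depth are not given in the sources used here. The deposited score is the peak caller's own value for each peak. The lowest score lay between 50.0 and 50.06 in the 22 lists. The scale is not stated, so scores were used only to rank, filter or compare peaks within a list. The depth of sequencing is unknown, and no interval that needs it is given. The number of peaks in a list depends on read depth, on the quality of the precipitation and on the cutoff as well as on the tumour, and these cannot be separated from peak lists. A gain or loss of DNA copies can also change how many peaks pass a cutoff, and whether a control library corrected for it is not stated.

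The lists held 456432 peaks, of which 449187 lay on the 22 autosomes. Peaks on X and Y (1.59% of the total) were left out because the samples are labelled as human tumours. No peaks overlapped within a list. The 16 tumours with at least 10000 peaks entered the main comparisons with 435251 autosomal peaks, and the other 6 lists were described separately. Coordinates are given 1-based on hg19, as the files hold them. No annotation or sequence of hg19 was used here, and the gene table at hand is on another assembly, so regions are named by position and no gene, exon or promoter is assigned to them. For the same reason 4 planned results (promoter against distal peaks, marking of 20 fixed gene lists including cell type markers, covariation of those lists between tumours, and sequence motifs) were not run.

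Peaks of the 16 tumours were merged into regions when they overlapped by at least 1 bp, and the number of tumours with a peak in each region was counted. A region present in at least 75% of the tumours (12 of 16) is called shared and one present in 1 tumour private. The chance level came from 20 shuffles that moved each peak to a random place on its own chromosome, whose length was taken as the largest coordinate in any list. Places were drawn evenly, stretches without sequence included. Peaks that recur between lists for technical reasons would also exceed this level, in every comparison with shuffles given here. For stitched domains, peaks at most 12500 bp apart were joined within a tumour, domains were ranked by the length covered by peaks, and the 500 longest of each tumour were merged across tumours. Shuffled domains gave the chance level. For comparisons that need lists of equal length, the 10000 highest scoring autosomal peaks of each tumour were used, and a peak counted as found in another tumour when its centre lay in a peak of that tumour. Paired differences were tested over tumours by a two-sided permutation test that enumerated all 65536 sign flips, so that 3.05e-05 is the smallest p it can give. Correlations over tumours were tested with 100000 random pairings, or with all pairings (exact) below 10 tumours, two-sided. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Intervals for shares are 95% Wilson intervals and cover counting error only.

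The named regions and domains follow a rule fixed before the data were examined. They are the 15 regions present in all tumours with the best median score rank, and the 15 domains among the 500 longest in most tumours, with ties broken by the median covered length. Peak widths of shared and private peaks, sharing by peak score, chromosome shares and the sets without particular tumours were added after seeing the data. The alternatives tried were a score of at least 100, other minimum list lengths, equal list lengths, other overlap rules, other joining distances and other numbers of domains. Some labels carry codes that start with 0 (10 tumours) or 1 (7 tumours), which could follow separate collections. The codes of 3 samples start with a letter, and what this means is not stated. One of these codes, in the set of 16, resembles the name of an established cell line, and whether that sample is a cell line is not known here. They were kept because they are labelled as tumours like the rest, and 2 of them are in the set of 16. Relations over tumours were recomputed within these where 6 or more tumours were present.

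The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. It was tested on simulated data. With peaks of the 16 tumours at random places, 100% of 1353 planted shared regions and 100% of 60 planted domains were recovered, and 2 unplanted regions were called. The planted regions and domains lay above the limits for a call, so their recovery checks the computation and not its sensitivity to weaker signals. The paired test passed the threshold in 5.3% of 1000 simulations without an effect. These used normally distributed values, fewer than the 16 tumours, and not peak data. With chromosome names permuted among the peaks of the 16 tumours, r between the shares of chromosomes 7 and 10 was 0.18, and it was -0.96 after an opposite change was planted.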

Results

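The series examined H3K27ac, a histone mark of active promoters and enhancers, in glioblastoma tumours by ChIP-seq. Each of 22 tumours was represented by 1 list of peaks, and the comparison that the design implies is which acetylated regions tumours have in common and in which they differ. The lists held between 70 and 47851 peaks, with a median of 23727. Autosomal peaks covered between 0.0589 and 102.7 Mb of the genome (median 33.3 Mb), and their median width in a list ranged from 580 to 2367 bp. The read depth behind the lists is unknown. The labels do not say whether every sample came from a separate patient. The p-values over tumours treat the samples as independent, and they are too small if some samples share a patient.

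**Figure D1:**
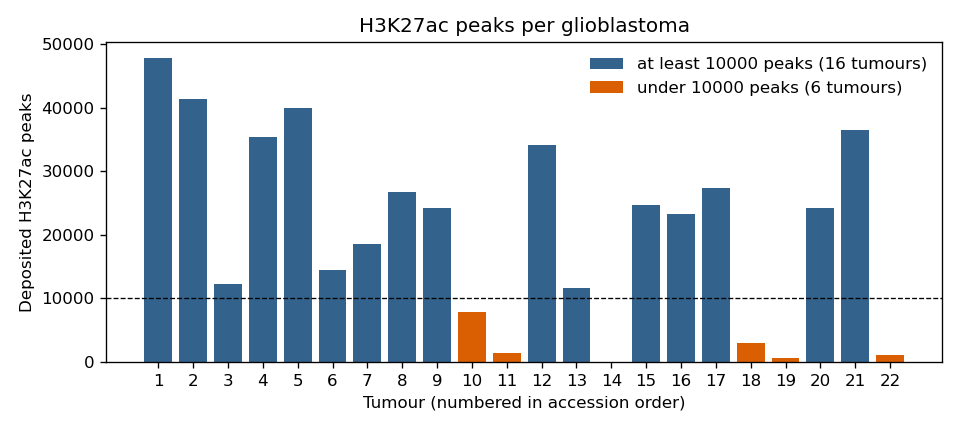
Number of deposited H3K27ac peaks (vertical axis) in each of the 22 tumours (horizontal axis), with the minimum of 10000 peaks as a dashed line. The 16 tumours above the line held 11625 to 47851 peaks, and the 6 below it held 70 to 7895.

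Tumours with at least 10000 peaks had 27645 ± 10727 peaks (SD, n = 16) with a median width of 1365 ± 320 bp (SD, n = 16). Whether longer lists held wider peaks depended on the tumours included. Over all 22 tumours, Pearson's r between log10 of the peak number and the median width was 0.41 (permutation p = 0.0626, adjusted 0.0626 over 3 sets) and Spearman's rho was 0.47 (permutation p = 0.0286, adjusted 0.0429). Without the 2 tumours farthest from the median peak number, r was 0.028, so the pooled r rested on those tumours. Spearman's rho was not recomputed without them. Within the 10 tumours whose label code starts with 0, r was 0.84 (permutation p = 0.0031, adjusted 0.0093) and rho was 0.83, and r was 0.97 without the 2 farthest. Within the 7 whose code starts with 1, r was 0.83 (exact permutation p = 0.0438, adjusted 0.0626), rho was 0.54 (exact permutation p = 0.236) and r without the 2 farthest was 0.20.

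The first comparison asked which regions were acetylated in many tumours. Autosomal peaks of the 16 longer lists merged into 105393 regions covering 227.9 Mb. Of these, 53125 regions (50.4%) were seen in 1 tumour, 9747 regions (9.25%) were shared by at least 12 tumours and 1785 of the latter were present in all 16. The distribution had 2 ends: the number of regions fell from 14814 in 2 tumours to 1442 in 11 tumours and was higher again at 2345 in 15 tumours. Regions seen in 1 tumour came unevenly from the lists. They held 30.3% of the 23931 autosomal peaks of tumour 20 and 26.5% of the 35569 of tumour 21. They also held 20.4% of the 38821 of tumour 5 and 16.3% of the 46694 of tumour 1. No other list was above 12.1%, so a few lists supplied most of these regions. Shared regions covered 44.9 Mb, or 1.56% of the autosomal span. They were wider than private ones, with a median merged width of 3512 bp against 990 bp, although merging more peaks widens a region by itself.

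**Figure D2:**
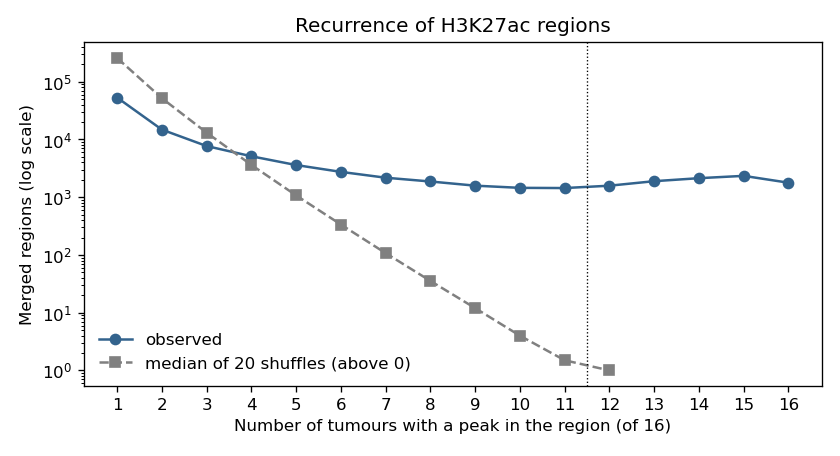
Number of merged H3K27ac regions (vertical axis, log scale) by the number of tumours with a peak in them (horizontal axis, of 16). Circles are observed values and squares the median of 20 shuffles of peak positions, and the dotted line marks the limit of 12 tumours for a shared region. The observed curve levels off and is at 1785 regions in all 16 tumours, where no shuffled region was found.

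In 20 shuffles of the peak positions, at most 2 regions reached 12 tumours, against 9747 observed. This sets the count against evenly random places only. A single tumour's peaks divided unevenly between shared and private regions. Peaks in shared regions made up 44.6% ± 13.3 (SD, n = 16) of a list, from 23.6% to 68.4%, and peaks in private regions made up 10.96% ± 8.35 (SD, n = 16), from 2.90% to 30.3%. The part in shared regions tended to be lower in longer lists. It was lowest in the longest list (tumour 1, 46694 autosomal peaks) and highest in a short one (tumour 3, 12114). The shortest list (tumour 13, 11549) had 53.5%. The spread thus cannot be read as a difference between tumours apart from list length. The single peaks in shared regions were also wider than those in private regions within the same tumour. The ratio of their median widths was 1.93 ± 0.39 (SD, n = 16) and lay above 1 in 16 of 16 tumours (paired permutation test, two-sided, p = 3.05e-05, the smallest possible). A wide peak meets other peaks more easily, so peaks were also classed by whether other tumours had a peak centre within 1000 bp of their own centre, and the ratio was then 1.91 ± 0.37 (SD, n = 16). Score differed in the same direction. The median score was higher in shared than in private regions in every tumour, at 82.8 to 890.1 against 55.7 to 87.4. The ratio was not computed at equal score, so a difference in width cannot be told apart from one in score. The number of shared regions was 3715 when only the 10000 highest scoring peaks of each tumour were used, and 1685 when all 22 tumours were included and 17 had to hold a region.

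The 15 regions that ranked highest by score among those present in all 16 tumours lay on 8 chromosomes, and 4 of them were on chromosome 7 and 3 on chromosome 11. The best median rank was 31 within a tumour's list, for a 13936 bp region on chromosome 7 from 5456993 to 5470928. It was followed by a region of 53199 bp on chromosome 22 from 46438261 to 46491459, with a median rank of 35.5. The worst rank of this region in any tumour was 413, the best such value of the 15, whereas the chromosome 7 region fell as low as rank 8947. The chromosome 22 region was also the widest of the 15, and a wider region can hold more peaks from which the best is ranked. The other chromosome 7 regions ran from 104649548 to 104659408 (median rank 62), from 130788084 to 130797831 (median rank 63) and from 39987372 to 39993568 (median rank 131). On chromosome 11, 3 regions lay within 94 kb of each other, from 65182092 to 65204643 (median rank 66), from 65252693 to 65262872 (median rank 140.5) and from 65263117 to 65275570 (median rank 95.5).

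Of the remaining 7 regions, chromosome 12 held one from 122230210 to 122245297 (median rank 63.5) and one from 125397845 to 125409356 (median rank 160). Chromosome 19 held one from 12898523 to 12905756 (median rank 66) and chromosome 1 one from 234734256 to 234750799 (median rank 66.5). Chromosome 9 held one from 131898383 to 131907071 (median rank 115) and one from 132242356 to 132264778 (median rank 124.5). The last was on chromosome 5 from 90670509 to 90681124 (median rank 162.5). When peaks had to cover at least 50% of the merged region, 6 of the 15 fell below the limit of 75% of tumours. These were the chromosome 7 region that starts at 104649548 (62.5%), the chromosome 11 regions that start at 65182092 (68.8%) and 65263117 (50%), both chromosome 12 regions (56.3% and 43.8%) and the chromosome 5 region (50%). Ranks refer to lists of different lengths and are given to describe each region, not to compare tumours.

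The second comparison asked where peaks clustered into long acetylated domains. The 500 longest stitched domains of each tumour merged into 2661 domains, of which 1326 (49.8%) were in the top 500 of 1 tumour, 74 in that of at least 12 tumours and 8 in that of all 16. Shuffled domains reached 12 tumours 0 times in 20 shuffles. The shortest of a tumour's 500 domains covered between 3.51 and 20.9 kb, so the limit for a long domain differed between tumours.

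The domain with the longest median coverage among the 8 common to all tumours lay on chromosome 22 from 46390117 to 46548026. Peaks covered 73.6 kb of it in the median tumour (range 27.2 to 108.0 kb), in a median of 19 peaks. It contained the chromosome 22 region that ranked second by score. Chromosome 19 held a domain from 13043141 to 13240387 with a median of 41.6 kb covered (range 6.16 to 127.8 kb) and another from 1066592 to 1326426 with 28.9 kb (range 7.18 to 96.4 kb). A domain on chromosome 5 from 139012766 to 139208860 had a median of 37.0 kb covered (range 6.47 to 117.6 kb). The domain on chromosome 11 from 65182092 to 65275570, with 30.8 kb covered (range 17.7 to 64.6 kb), contained the 3 chromosome 11 regions named above. The other domains found in all tumours were on chromosome 1 from 33763949 to 33940249 (25.2 kb), on chromosome 9 from 132193412 to 132269820 (20.7 kb) and on chromosome 17 from 43158106 to 43254228 (16.5 kb).

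A further 9 domains were among the 500 longest in 15 of 16 tumours. The 7 with the longest median coverage were on chromosome 3 from 50230207 to 50397822 (38.1 kb), chromosome 17 from 17565879 to 17834225 (32.7 kb) and from 8013046 to 8131086 (20.4 kb), chromosome 20 from 45884682 to 46022116 (24.6 kb), chromosome 14 from 77466657 to 77544046 (22.96 kb), chromosome 19 from 12867973 to 12918515 (17.8 kb) and chromosome 12 from 6999408 to 7088251 (17.4 kb). In all, chromosomes 17 and 19 held 3 each of the 15 named domains, and 6 of the 15 top-scoring regions lay inside one of these domains. Some named domains depended on the joining distance or on the number of domains taken. With peaks joined at 5000 bp, the chromosome 17 domains that start at 43158106 and 17565879 were found in 31.3% and 68.8% of tumours and the chromosome 12 domain in 50%, below the limit of 75%. With the 200 longest domains, the chromosome 19 domain that starts at 12867973 was found in 56.3% of tumours and the chromosome 12 domain in 50%. The count of 74 shared domains moved to 24 when only the 200 longest domains of each tumour were taken and to 216 with the 1000 longest.

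The third comparison asked how far the strongest peaks of one tumour were found in another. Each pair of tumours was given the mean over both directions. With the 10000 highest scoring peaks of each tumour, 46.5% of peaks were found in the other tumour in the median pair, and the 120 pairs ranged from 22.7% to 69.5%. No pair came close to complete overlap, but lists from 1 patient may also overlap only in part, so a repeated patient is not excluded. Each list was counted as a separate sample. Shuffled peaks gave a mean of at most 0.959%. Pairs within the 9 tumours whose label code starts with 0 had a median of 50.7%, pairs within the 5 whose code starts with 1 had 45.5%, and pairs between these sets had 46.4%. Tumour 20 shared less with the rest than any other, with a mean of 29.1% against 35.4% to 53.5% in the other 15.

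**Figure D3:**
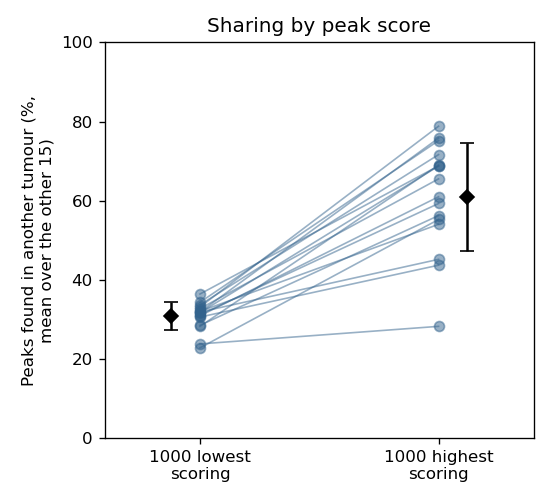
Share of peaks found in another tumour (vertical axis, percent, mean over the other 15 tumours) for the 1000 lowest and 1000 highest scoring of each tumour's 10000 peaks (horizontal axis). Lines join the values of 1 tumour, and diamonds with bars show the mean and SD of 16 tumours. The line rises in all 16 tumours, from a mean of 30.9% to 61.0%.

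High scoring peaks were shared more often than low scoring ones. The share of a tumour's peaks found in another tumour was taken for each of the other 15 tumours and averaged. This mean share was 61.0% ± 13.6 (SD, n = 16) for the 1000 highest scoring peaks. For the 1000 lowest scoring of the 10000 it was 30.9% ± 3.57 (SD, n = 16). The difference of 30.2 percentage points ± 11.8 (SD, n = 16) had the same direction in 16 of 16 tumours (paired permutation test, two-sided, p = 3.05e-05, the smallest possible). A peak counted only when its centre lay in the other tumour's peak. Its own width thus did not add to the overlap, but the width of the other tumour's peak did. The 1000 lowest scoring peaks lie at the rank cut, so the same site may fall just outside another tumour's list. Part of the difference may follow from this cut. Tumour 16 went the other way on a second measure, since 32.8% of its 1000 highest scoring peaks had their centre in no other tumour's top peaks, against 13.54% of its 10000, whereas this private share was lower among the highest scoring peaks in the other 15 tumours.

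The last comparison asked how acetylated regions were spread over the chromosomes. Among the 10000 highest scoring peaks, density was highest on chromosome 19 with 8.61 ± 2.09 peaks per Mb (SD, n = 16) and chromosome 17 with 7.41 ± 0.90, both gene-dense chromosomes. It was lowest on chromosome 13 with 1.66 ± 0.48 and chromosome 4 with 1.86 ± 0.32. Chromosome length was taken as the largest coordinate in any list, and stretches without sequence were not left out. These lower the density of some chromosomes, so the order of close values is not firm. With all deposited peaks, those in shared regions lay on chromosomes 17 and 19 more often than private peaks of the same tumour. Chromosome 19 held 6.06% ± 0.53 of a tumour's shared-region peaks and 2.26% ± 1.84 of its private peaks (SD, n = 16; adjusted permutation p = 0.00067), and it was higher among shared peaks in 15 of 16 tumours. Chromosome 17 held 6.58% ± 0.28 and 3.57% ± 1.56 (SD, n = 16; adjusted permutation p = 0.00067), with the same direction in 16 of 16 tumours.

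Of the 22 autosomes, 6 held a larger part of shared than of private peaks and 5 a smaller part after adjustment over the 22 tests. The larger shares were on chromosomes 1, 12, 16, 17, 19 and 20, and the smaller ones on chromosomes 4, 8, 13, 18 and 21. Chromosome 8 had 3.62% ± 0.17 of shared and 5.45% ± 1.82 of private peaks (SD, n = 16; adjusted permutation p = 0.0058), lower in all but 3 tumours. On chromosome 7, private peaks averaged 10.4% ± 13.04 against 5.34% ± 0.38 of shared peaks (SD, n = 16), but the median private share was 5.33% and the difference did not pass the test (adjusted permutation p = 0.117). The number of chromosomes that differed was 1 with a score of at least 100, 2 with the 5000 highest scoring peaks and 7 with the 10000 highest scoring peaks. In these 3 settings the adjusted permutation p was 0.0013, 0.316 and 0.0121 for chromosome 17, 0.0506, 0.316 and 0.0974 for chromosome 19, and 0.296, 0.404 and 0.0383 for chromosome 8.

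**Figure D4:**
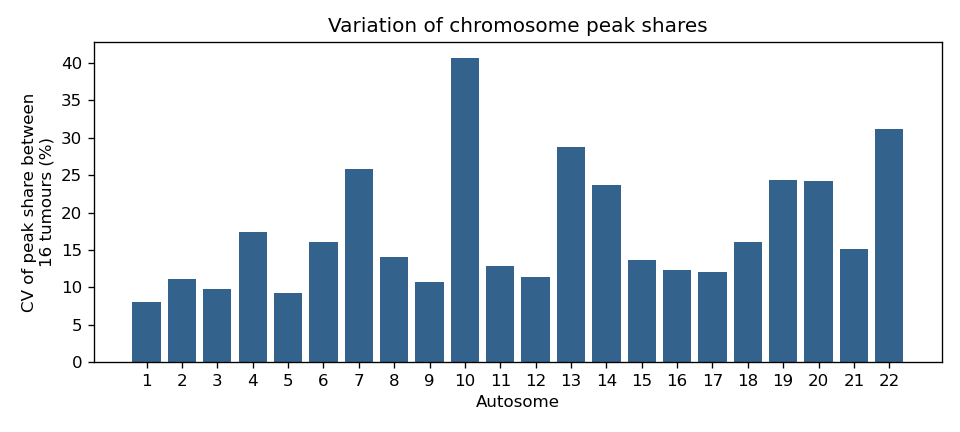
Coefficient of variation (CV, vertical axis, percent) of each autosome's share of the 10000 highest scoring peaks over 16 tumours (horizontal axis, chromosome). Chromosome 10 varied most (40.7%), and chromosome 1 least (7.99%).

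The part of a tumour's peaks that each chromosome carried is described without a test. Chromosome 10 held 2.99% ± 1.22 of peaks (SD, n = 16), from 0.93% to 4.95%, and its CV of 40.7% was the highest of the 22. Chromosomes 22, 13, 7, 19, 20 and 14 followed with CVs of 31.2%, 28.8%, 25.8%, 24.3%, 24.3% and 23.7%. The other 15 autosomes had CVs between 7.99% and 17.5%. Chromosome 7 held 6.67% ± 1.72 of peaks (SD, n = 16), from 4.34% to 10.35%.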

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

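The tests on short lists and their interval bounds were chosen after the overlaps had been seen, and those on the tumour that shared fewest peaks were set before their results. The 6 lists with under 10000 peaks were left out of the set of 16. Tumour 10 entered the alternatives with at least 5000 peaks, and all 6 entered the one with 22 tumours and the peak numbers and widths. Of these lists, 5 held peaks in the regions shared by the longer lists far above the shuffled level. The share was 56.3% of 7826 autosomal peaks in tumour 10 (95% Wilson interval 55.2% to 57.4%, highest of 20 shuffles 2.44%). It was 33.2% of 1421 in tumour 11 (30.8% to 35.7%, shuffles up to 2.81%), 55.2% of 2863 in tumour 18 (53.4% to 57.0%, shuffles up to 3.32%), 39.0% of 651 in tumour 19 (35.3% to 42.8%, shuffles up to 3.23%) and 77.3% of 1106 in tumour 22 (74.7% to 79.7%, shuffles up to 2.89%).

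Peaks at chance positions were tested as an explanation of these short lists. In 5 of the 5 lists of 651 to 7826 peaks the lower bound lay above the highest shuffle, which argues against evenly random positions for these lists as a whole. It does not tell tumour signal from peaks that recur for technical reasons. For the list of 69 autosomal peaks the share was 4.35% (1.49% to 12.02%) with a shuffled median of 1.45% and a highest shuffle of 5.80%, so too few peaks keep this open. A low read depth or a weak precipitation may have shortened all 6 lists, and neither can be read from peak lists. No biological explanation was tested.

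Tumour 20 shared fewest peaks with the others, with a mean over its pairs of 29.1% of the 10000 highest scoring peaks, averaged over both directions. Of its own 10000, 42.3% had their centre in no other tumour's top peaks, against 2.90% to 25.2% in the other 15. Such peaks are called private in the tests below. By the merged regions of all deposited peaks the gap was smaller, with 30.3% of its peaks in private regions against 26.5% in tumour 21, the next highest. Its list held 24151 peaks, and their median width of 1841 bp was the largest of the 16 tumours. The median width of its peaks in private regions, 1474 bp, was also the largest. Chance positions of weak peaks alone would leave its strongest peaks no more private than those of other tumours. Of its 1000 highest scoring peaks, 38.0% were private (95% interval 35.0% to 41.0%), above the highest of the other tumours at 32.8%. Its private peaks were thus not only weak ones. These 1000 belong to the 10000 by which the tumour was picked, and noise at every rank would give the same result. The test therefore cannot argue against noise in the whole list. A few dense clusters of peaks were argued against because its 10 densest windows of 1 Mb held 3.64% of its 4226 private peaks (3.12% to 4.25%). Its label code starts with a letter, although it is not the code that resembles the name of a cell line. A different cell makeup or a wrong label may account for it, and both stay open because no annotation of the build was used here. No biological explanation was tested.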

How the results depend on the processing

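Apart from the planned choices for regions and domains, the alternatives for peak score, chromosomes and particular tumours were chosen after seeing the data. The number of shared regions (9747) stayed within 1.5 times under 5 of 9 alternatives, and was 4241 with a score of at least 100, 3715 with the 10000 highest scoring peaks, 1685 with all 22 tumours (at least 17 of 22 needed) and 2687 when peaks had to cover at least 50% of the merged region. At most 10 shuffled regions were called in any of these settings. The number of shared domains (74) stayed within 1.5 times under 8 of 10 alternatives and was 24 with the 200 longest and 216 with the 1000 longest domains, which follows from how many domains were taken. Of 135 values for the 15 named regions under the alternatives, 129 stayed within the interval of the main value. Of 150 values for the named domains, 143 did. The named regions were chosen for presence in every tumour of the main set, so settings that only leave tumours out could not change their values. The same holds for the named domains found in every tumour. The interval is also wide, since a region found in 81.8% of all 22 tumours still lay within it. These counts are thus a weak check of stability. The lowest values were 43.8% of tumours for a region and 31.3% for a domain. The ratio of the widths of shared and private peaks was 1.92 and 1.91 when peaks were classed by their centres. Score was not held equal in either. The difference in sharing by peak score kept its direction and its call under all 8 alternatives, although the lists end at a cut in each of them. The number of chromosomes that differed between shared and private peaks (11) was 1 with a score of at least 100, 2 with the 5000 highest scoring peaks and 7 with the 10000 highest scoring peaks, and stayed within 1.5 times under the other 4. The negative correlation of chromosome 7 and 10 shares kept its sign in all 10 alternatives. It no longer passed after adjustment over the 231 pairs with the 5000 highest scoring peaks (r = -0.72, adjusted permutation p = 0.163), without tumour 20, which shared fewest peaks (r = -0.79, adjusted p = 0.113), without the 2 tumours whose label code starts with a letter, tumour 20 among them (r = -0.77, adjusted p = 0.169) and without each tumour's 5 densest windows of 1 Mb (r = -0.72, adjusted p = 0.0744). Fewer tumours or peaks entered those correlations, but the call was kept with only the 12 tumours of at least 20000 peaks (r = -0.89, adjusted permutation p = 0.0254). Why the call was lost in the other settings was not tested further. The alternatives for promoters, gene lists, list covariation and motifs were not run for want of an annotation of the build. No paired analysis between groups was possible because all samples belong to 1 group, and the paired tests compare peaks within a tumour. List length limits all counts, since regions missed in a short list cannot be told from regions that were not acetylated.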

Other observations

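The share of peaks on chromosome 10 moved against that on chromosome 7 between tumours. This pair was singled out after the values were seen, with the background that gain of chromosome 7 and loss of chromosome 10 are frequent in glioblastoma. Over 16 tumours Pearson's r was -0.82 (permutation p = 0.00016, adjusted 0.037 over 231 chromosome pairs) and Spearman's rho was -0.79 (permutation p = 0.00049, adjusted 0.0502, which did not pass). By rho chromosomes 4 and 22 were further apart (rho = -0.80, adjusted permutation p = 0.0502). By r the pair 7 and 10 was the most negative of the 231 pairs and the 1 pair that passed, while 25 pairs had an unadjusted p under 0.05. Without the 2 tumours farthest from the median chromosome 10 share, r was -0.84. The largest gap in the chromosome 10 shares, 0.96 percentage points, set the 3 lowest tumours apart, and among the other 13 tumours r was -0.74 (permutation p = 0.0044) and rho was -0.64 (permutation p = 0.021). Within the 9 tumours whose label code starts with 0, r was -0.78 (exact permutation p = 0.0145), and the 5 whose code starts with 1 were too few. Without the 2 tumours of unstated code, which starts with a letter, r was -0.77 and did not pass (adjusted permutation p = 0.169).

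The tests of this pattern were chosen after the shares had been seen, and that of the first principal component of the other chromosomes was added after the result for list length was known. Each technical account met an r below -0.5 with every tumour left out in turn, which argues against it as the whole cause. For shares that sum to 100, r was -0.80 with chromosome 7 peaks left out of the total (at most -0.75). The partial r was -0.82 given the length of the peak list (at most -0.76), which had an r of -0.055 and 0.016 with the shares of chromosomes 7 and 10. It was -0.81 given the first principal component of the other 20 chromosomes (at most -0.76), which held 29.5% of their variance and had an r of 0.20 and -0.13 with these shares. Neither follows both shares, so neither removes much, and other gradients stay open. For a few dense clusters of peaks, r moved to -0.72 without each tumour's 5 densest windows (at most -0.63), which ended the adjusted call (adjusted permutation p = 0.0744), so part of the size of r may come from them. Whole-chromosome dosage predicts that windows along a chromosome move together. The mean pairwise r among the 13 windows of 10 Mb on chromosome 10 was 0.50, above the 95th percentile of random windows at 0.10, and it was 0.32 on chromosome 7 against 0.086. This is consistent with copy number differences between tumours reaching the peak lists, as a hypothesis, but 18 of 22 chromosomes passed that percentile, copy number was not measured here, and an effect of the control library stays open.

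The 7 autosomes whose peak share varied most between tumours (10, 22, 13, 7, 19, 20 and 14) were also the 7 with the highest mean r among their own windows, with chromosome 19 at 0.85 and chromosome 22 at 0.69. Counting noise lowers r where a share varies little, so part of this match follows from the measure. Chromosome 9 had the lowest mean r, at 0.0076. Other pairs of chromosomes with a large r were 3 and 19 (r = -0.74, adjusted permutation p = 0.098), 16 and 22 (r = 0.72, adjusted p = 0.098) and 4 and 22 (r = -0.73, adjusted p = 0.098), none of which passed.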
